A study of Mus musculus with 4 samples.

How the data were processed

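The series holds 4 arrays of total RNA from ICR mouse organ primordia at embryonic day E11.5: lung, esophagus, stomach and intestine, 1 array each. The organ was taken from the sample titles and tissue labels. The extraction protocol of all 4 samples speaks of stomach, and the stomach title is spelled unusually; neither was used to assign the organ. Per the labels' protocols, RNA was isolated with an RNeasy micro kit, labelled with Cy3 by the Agilent Low Input Quick Amp kit and hybridised in 1 colour. Low-input amplification of small samples can add differences between arrays that these data cannot separate from the organ, because no organ was measured more than once.

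Per the file headers, the scans were read with Agilent Feature Extraction 10.5.1.1 under protocol GE1_105_Dec08 on array design 014868, whose sequences refer to build mm8. The deposited signals are spot intensity values on a linear scale: the processed signal is background-subtracted and detrended within the array, per the file headers, and it is not scaled between arrays. The deposited series table holds log2 values. Set against the scanner values it matched log2 processed signal minus the array's 75th percentile (r of 0.99996 to 0.99998 by array, with medians of −3.55, −2.96, −3.16 and −3.46 for lung, esophagus, stomach and intestine), and its scale, centring and direction are known from that match only. It served as an alternative.

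The value used was log2 processed signal minus the array's 75th percentile over non-control probes. Spots with an outlier flag were left out, copies of a probe were averaged, and 69 probes were dropped because every spot on some array had such a flag. No spot was saturated. Of 41174 probes, 24375 (59.2%) were given 1 gene symbol by matching their accession, without version, to the RefSeq gene table of assembly GRCm38.p6, and 16799 had none and were not named. That table was used for names only and no coordinates are given, since the array design refers to another build. Of 16995 genes with a symbol, 14518 had a probe well above background on at least 1 array and 9497 on all 4. A gene's value was that of its brightest probe, by mean log2 signal over the arrays; 5767 genes had more than 1 probe.

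Where a gene was not well above background on an array, that array entered at the higher of its own value and the array's lowest signal well above background, so that the fold is a lower bound. These lowest levels were −2.39 in lung, −5.75 in esophagus, −5.78 in stomach and −6.92 in intestine. No fold was given where both arrays were below background. Genes were counted when at least 2-fold apart, and again at 4-fold, between organ pairs, above or below every other organ, shared by a pair, and ordered from esophagus to intestine. With 1 array per organ there was no test, and thresholds are sizes only. The genes named were set by a rule fixed before the data were examined: for each organ the 10 of largest margin above and the 5 of largest margin below the other organs, leaving out clone names and genes whose bright probes disagree in sign, up to 4 per shared or ordered set, up to 4 per gene list, and Nkx2-1, Sox2, Barx1 and Cdx2 in every organ. A gene that falls under this rule is not reported here. Trpv6, Maats1, Fgf10 and St8sia4 are the whole of their set. Some further list members are named beyond that rule, chosen after their values were seen, among them Nppb, Myl2, Gata5, Cldn18, Ddx3y, Eif2s3y and Kdm5d and the lung levels of Hoxb5 and Hoxb6.

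For 33 gene lists fixed before the data were examined (405 different genes, 304 of them measured), the median over members of an organ's log2 value minus the mean of the others was set against 10000 random lists of the same size matched on mean level in 20 bins; the percentile describes these arrays and is not a p-value. After the arrays had been seen, this step departed from the plan: values were raised to the lung array's lowest level, −2.39, on all arrays, and genes at that level on every array were left out, which leaves 11073 genes, because the lung array cannot resolve lower levels. Tolerances for calling a value the same under another setting (the SD of r over the pairs, a bootstrap error of a list median, the spread over spots) were also set then.

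The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1. They were tested on simulated data: in 14518 genes with 200 changed by known amounts, all changed genes were recovered where the mean level lay above the lung array's lowest level, while below it 30.4% were recovered at a log2 change of 1.5, 47.1% at 2 and 70.0% at 3, and 0 of 14318 unchanged genes were called. Unchanged simulated genes had the same level on all arrays, and the only error was the spread over spots. Full recovery and the absence of false calls follow from that setting. They give no error rate for the real arrays, where probes of a gene and samples can differ by more. Of 200 random lists of 12 genes, 193 fell between the 2.5 and 97.5 percentiles.

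The alternatives planned were normexp background correction with an offset of 50, quantile normalization, centring on the median, the 75th percentile over probes well above background on all 4 arrays, the deposited series table, only genes bright on all 4 arrays, no filter on dim probes, the mean of all probes of a gene, and leaving out saturated probes. Normexp was planned on mean signals and was run on median signals, which these files hold. List values were raised to the highest of the arrays' lowest levels under normexp as well, so a small list median there does not show a reversal. Leaving out each array in turn was added after the data had been seen. Median centring moved the middle of all genes by 0.26 in lung, −0.32 in esophagus, −0.12 in stomach and 0.18 in intestine relative to the mean of the arrays, and the percentile over probes bright on all 4 arrays moved it by −0.18 in lung and 0.12 in esophagus.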

Results

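RNA from 4 organ primordia of the ICR mouse, an outbred laboratory strain, was measured at embryonic day E11.5, when the lung, esophagus, stomach and intestine are distinct segments of the gut tube. Each organ was represented by 1 array, read in 1 colour (Cy3), and the 4 arrays shared 1 slide and 1 scan. There was therefore no replicate of any organ: every value below describes 1 sample, no test between organs could be made, and no p-value is given. Precision is limited by the number of arrays. The only error the arrays give is within an array, where the median SD over 10 copies of a probe was 0.10 on the log2 scale for lung, 0.08 for esophagus, 0.08 for stomach and 0.07 for intestine; it leaves out differences of dissection, RNA and labelling.

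The lung array was much dimmer than the others. In lung, 39.0% of 43379 spots were well above background, against 69.3% in esophagus, 67.9% in stomach and 74.0% in intestine, and the 75th percentile of the signal was 33.4 in lung against 393, 334 and 1023. The spike-in control spots, RNA added in fixed amounts, were dimmer in lung as well: their median signal was 78.8, and it was 21.7-fold higher on the esophagus array, 20.7-fold on the stomach array and 34.4-fold on the intestine array. Genes well above background numbered 9524 in lung, 13283 in esophagus, 13374 in stomach and 14279 in intestine. Levels are given as log2 signal relative to the array's own 75th percentile, and where a gene was not well above background its fold is a lower bound, written "at least".

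Genes that mark each organ were read first as a check of the labels, since the extraction protocol of all 4 samples speaks of stomach. Nkx2-1, a transcription factor of the lung and thyroid, was 11.9-fold higher in lung than in the next organ, esophagus. Barx1, a transcription factor of stomach mesenchyme, was 11.9-fold higher in stomach than in esophagus. Cdx2, a transcription factor of the intestinal epithelium, was at least 19.5-fold higher in intestine than in any other organ. Sox2, a transcription factor of the foregut, stood at 1.09 in esophagus and 0.63 in stomach, and at −1.77 in lung and −2.56 in intestine. Nkx2-1, Barx1 and Cdx2 were each highest on the array whose label names their organ.

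The first comparison asked how alike the organs were. Across 14518 genes, esophagus and stomach (Pearson r = 0.967) and stomach and intestine (0.966) lay closest, followed by esophagus and intestine (0.939), and each pair with lung lay between 0.928 and 0.931; genes are not independent replicates, and these values describe pairs of arrays. Genes at least 2-fold apart numbered 1360 between esophagus and stomach, 1711 between stomach and intestine and 2871 between esophagus and intestine. They numbered 2696 between lung and esophagus, 2508 between lung and stomach and 2146 between lung and intestine. Fewer genes could be compared in the lung pairs, 10513, 10503 and 10416 in that order, than between esophagus and intestine, 13900. The share 2-fold apart was 25.6% for lung and esophagus, 23.9% for lung and stomach and 20.6% for lung and intestine. It was 20.7% for esophagus and intestine, 12.4% for stomach and intestine and 9.90% for esophagus and stomach. At 4-fold the counts were 310, 373 and 787 among the 3 gut segments and 419, 461 and 420 for lung against esophagus, stomach and intestine. The direction of these calls moved with the scaling. Lung against esophagus had 1706 genes higher and 990 lower, against 4537 and 459 when arrays were centred on the median, and 880 and 1518 when the percentile was taken over probes well above background on all 4 arrays. For lung against stomach the split was 1471 to 1037, and 2838 to 529 and 999 to 1427 under those scalings. For lung against intestine it was 1271 to 875, and 846 to 1241 under the second of them. Esophagus against stomach had 774 higher and 586 lower, and 567 and 966 under median centring. Esophagus against intestine had 1661 and 1210, against 958 and 3762 under median centring and 1283 and 1682 under quantile normalization. Stomach against intestine had 1038 and 673, against 586 and 1263, and 652 and 796, under the same settings.

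A second probe of the same gene gave a measure of how far a ratio can be trusted. Where the brightest probe gave a 2-fold difference, a second probe had the same sign for 92.5% of 241 genes between esophagus and stomach, 78.1% of 388 between stomach and intestine and 75.5% of 759 between esophagus and intestine. For the lung pairs the shares were 57.2% of 654 genes against esophagus, 60.2% of 528 against stomach and 68.1% of 451 against intestine. The SD of the difference between probes was 0.51 on the log2 scale for esophagus over stomach and 1.12 for lung over stomach, far above the SD over copies of 1 probe.

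**Figure D1:**
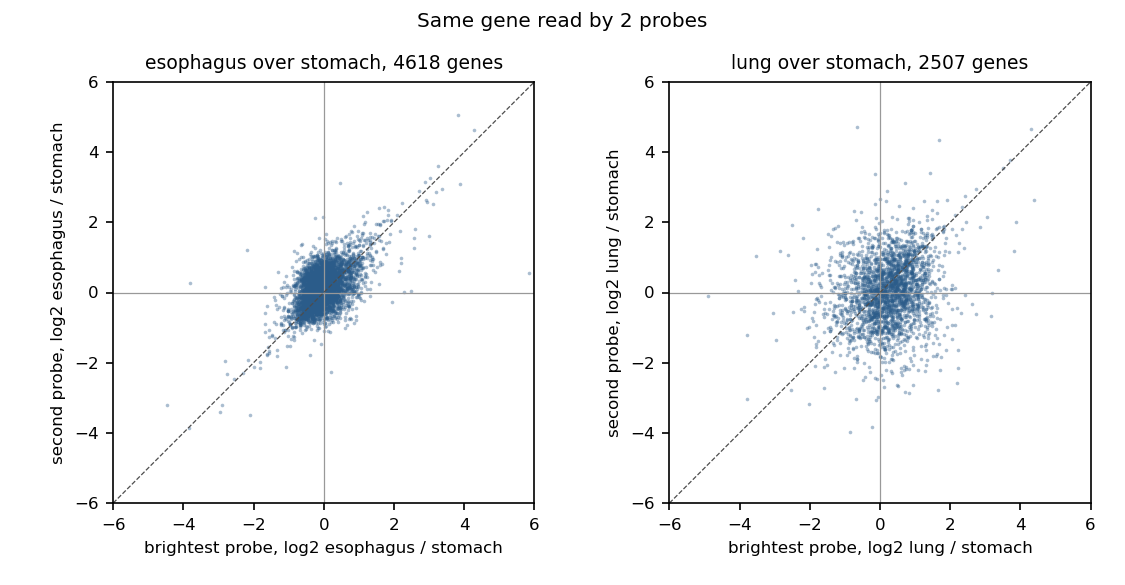
Log2 ratio of a gene by its brightest probe (x axis) against the ratio by a second probe (y axis), for esophagus over stomach in 4618 genes (left) and lung over stomach in 2507 genes (right), each point 1 gene well above background by both probes on both arrays, with the line of equality dashed. The correlation between probes is 0.59 on the left and 0.22 on the right.

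The second comparison asked which genes were higher in 1 organ than in each of the others. Lung had 646 genes at least 2-fold above every other organ, of which 69 were at least 4-fold above, and 325 genes at least 2-fold below every other. Among the genes of largest margin, Sftpc, which encodes surfactant protein C, was 14.7-fold above esophagus, Itgb3, the integrin beta 3 chain, 14.3-fold above esophagus, and Phf24 19.5-fold. The rest of the 10 genes of largest margin were Olfr815 (at least 72.1-fold), Snai3 (at least 34.96-fold), Sycp2 (at least 23.6-fold), Olfr564 (at least 21.3-fold), Kprp (at least 20.3-fold), Prl3d2 (at least 16.4-fold) and Olfr187 (14.9-fold). Among these 3 are olfactory receptors, and 8 of the 646 genes belong to the chemoreceptor families, against 0 of the genes higher in esophagus, stomach or intestine. Sycp2, Olfr564, Kprp and Prl3d2 stood in lung at −1.19, −1.34, −1.41 and −1.72, near that array's lowest level of −2.39. Their folds therefore depend on the scaling between arrays, whose 75th percentiles were 33.4 in lung and 393 in esophagus. Olfr815, Snai3, Olfr564, Kprp, Prl3d2 and Olfr187 had 1 probe each. The genes lowest in lung were Fam110a (at least 19.4-fold below the next organ), the RNA component Rmrp (14.8-fold), the hindlimb transcription factor Pitx1 (13.3-fold), the ribosomal RNA Rn28s1 (13.2-fold) and Lars2, the mitochondrial leucyl-tRNA synthetase (12.4-fold). Of 177 lung-high genes with a second probe, 84 (47.5%) had a second probe pointing the same way, against 38.1% of all genes with a second probe, and 29 were 2-fold by it. Here and below, the share of all genes counts second probes that were highest in the organ named, whatever the brightest probe showed. It is not a rate of agreement between probes. The split of 646 higher to 325 lower became 1127 to 174 under median centring and 332 to 540 under the percentile over probes bright on all 4 arrays. Without the intestine array the counts were 1091 higher and 618 lower, 104 of the higher at least 4-fold. Without the esophagus array 525 were lower and 148 at least 4-fold higher.

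The list of lung primordium genes, fixed before the data were examined, was higher in lung by a median of 1.70 (log2, lung minus the mean of the other organs; 15 measured genes), above all of 10000 random lists matched on level, and 8 of the 15 were at least 2-fold above every other organ. Under normexp background correction with an offset of 50, which exceeds the lung array's 75th percentile signal, the median was 0.58. Besides Nkx2-1 and Sftpc, these included Wnt2, a signal of lung mesenchyme, 3.60-fold above esophagus, and Tbx5, a transcription factor of heart, lung and forelimb, 2.04-fold above esophagus. Wnt7b was 2.51-fold higher and Tbx2 2.74-fold higher. The same list was also higher in esophagus, by 0.51 (percentile 99.9 among random lists; 2.18 without the lung array, with 18 measured genes), and lower in stomach, at −0.78, and in intestine, at −1.71, where Tbx5 was at least 43.1-fold below stomach. Nkx2-1 and Sftpc stood at −1.10 and −1.75 in esophagus and were not well above background in stomach or intestine. Whether such signals come from the esophagus itself or from neighbouring tissue in the dissected sample was not tested.

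Esophagus had 163 genes at least 2-fold above every other organ, 45 of them at least 4-fold, and 29 at least 2-fold below. Genes of striated muscle led. The heart myosin-binding protein Mybpc3 was at least 49.5-fold higher than in any other organ, the atrial light chain Myl4 22.2-fold, the heart myosin chain Myh6 at least 21.6-fold, the light chain Myl1 19.0-fold, the muscle glycolytic enzyme Pgam2 at least 15.9-fold and the muscle LIM protein Csrp3 at least 15.5-fold. Apobec2 was 11.7-fold higher, Nppa, which encodes the atrial natriuretic peptide, at least 11.6-fold, and Cox6a2 at least 11.2-fold. The lowest were Gipc2 (5.69-fold below the next organ), Hoxb6 (5.30-fold), Rerg (3.53-fold), Dnajc22 (3.36-fold) and Etv4 (3.36-fold), a transcription factor induced by FGF. Of 58 esophagus-high genes with a second probe, 27 (46.6%) had a second probe pointing the same way, against 25.8% of all genes with a second probe, and 15 were 2-fold by it. The split of 163 higher to 29 lower became 83 to 139 under median centring. Without the dim lung array the counts were 577 higher and 303 lower, with 168 at 4-fold, and without the stomach array 506 and 269, with 90 at 4-fold.

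The list of esophagus and stratified foregut epithelium genes was higher in esophagus by a median of 2.03 (8 measured genes, above all random lists; 0.25 under normexp and 1.51 under median centring), and 4 of the 8 were at least 2-fold above every other organ. It was also higher in stomach, by 0.73 (percentile 99.99 among random lists), where 2 of the 8 were at least 2-fold above every other organ. Pitx1 stood at 6.29 in stomach and 4.71 in esophagus. Trp63, a transcription factor of stratified epithelia, stood at 0.31 in esophagus and −2.15 in stomach, Krt5 at −0.59 and −2.46, Krt15 at 1.70 and 0.06, and Pax9 at −0.67 and −3.60. Heart muscle genes were higher on the esophagus array by a median of 3.54 (1.76 under normexp). All 9 measured members were at least 2-fold above every other organ. Among them, Myl7 stood at 6.06 against 2.57 in lung and Tnnt2 at 3.54 against 0.43 in lung. The remaining members, Nppb and Myl2, did not exceed on any array the lowest level the lung array could resolve, and were left out of the count. Skeletal muscle genes were higher by a median of 1.4985 (3 of 6 members 2-fold above every other organ; −0.10 under normexp, 0.62 under the percentile over probes bright on all 4 arrays and 3.20 under quantile normalization), smooth muscle genes by 1.33 (4 of 9), mesenchyme genes by 0.96 (3 of 14; 0.53 under median centring) and pharynx and thyroid genes by 2.13 (2 of 4; 0.0844 under normexp). The median of the esophagus list was 1.30, and that of skeletal muscle 3.11, without the lung array.

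Stomach had 54 genes at least 2-fold above every other organ, 9 of them at least 4-fold, and 48 at least 2-fold below. Nkx6-2, a homeobox gene also used in the neural tube, was 21.4-fold above intestine, Barx1 11.9-fold above esophagus, Prap1 9.66-fold above esophagus and Adra2a, an adrenergic receptor, 9.53-fold above intestine. Agr2 was at least 5.91-fold higher, Six2 4.88-fold, Kazald1 at least 4.54-fold, Nepn 4.33-fold, Hoxa7 3.99-fold and the Wnt receptor Fzd5 3.56-fold. The lowest genes were Cyp1b1 (4.99-fold below the next organ), Lyve1, a lymphatic and macrophage receptor (4.94-fold), Kcnk3 (4.89-fold), Lhx6 (4.26-fold) and albumin, Alb (4.07-fold). A second probe pointed the same way for 10 of 15 genes, against 10.9% of all genes with a second probe, and 2 were 2-fold by it. The stomach primordium list was higher in stomach by a median of 0.43 (10 measured genes, percentile 99.6 among random lists), by 0.84 without the lung array (13 measured genes), 1.01 without the intestine array and 0.58 without the esophagus array. The median was 0.17 under quantile normalization and under median centring, 0.19 with the mean of all probes and 1.12 with no filter on dim probes, and it lay below 0 under normexp (−0.10) and with only the genes well above background on all 4 arrays (−0.11). In that list Barx1, Six2, Isl1 and Nkx2-5 were highest in stomach, with Nkx2-5 at 1.05 against −0.09 in esophagus and Isl1 at 2.13 against 0.48 in lung. Gata5 and Cldn18 were highest in lung, at −0.43 and −1.67. The split of 54 higher to 48 lower became 31 to 52 under median centring. Leaving out the lung array gave counts of 152 and 124, without the esophagus array 245 and 142 and without the intestine array 161 and 202, and the higher at 4-fold numbered 33, 23 and 26.

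Intestine had 161 genes at least 2-fold above every other organ, 38 of them at least 4-fold, and 153 at least 2-fold below. Hand1, a mesodermal transcription factor, was at least 36.4-fold higher, Mab21l2 at least 33.9-fold, Lgals2 at least 27.6-fold, Cdx2 at least 19.5-fold, Tdh 18.2-fold, the intestinal homeobox gene Isx at least 16.2-fold, Nkx2-3, of gut mesenchyme, 13.8-fold, the pancreatic enzyme Cpa1 at least 12.4-fold, Hoxc9 at least 12.4-fold and Hoxa11 at least 11.2-fold. After Tbx5, the lowest genes were Scrg1 (17.2-fold below the next organ), Pappa (16.3-fold) and Myh8 (at least 13.6-fold). Of 43 intestine-high genes with a second probe, 29 (67.4%) had a second probe pointing the same way, against 16.0% of all genes with a second probe, and 21 were 2-fold by it. The intestine primordium list was higher by a median of 2.33 (10 measured genes, above all random lists), and 7 of the 10 were at least 2-fold above every other organ, including Vil1, a component of the brush border, at 0.67 against −2.79 in stomach, and Fabp1 at 0.05 against −2.93 in esophagus. Under normexp that median was −0.0848, and it was 1.22 with only the genes well above background on all 4 arrays. Liver genes were higher on the same array by a median of 2.58 (9 measured genes; 1.36 under normexp), 7 of the 9 at least 2-fold above every other organ. Alb stood at 2.98 in intestine, 1.98 in lung, −0.36 in esophagus and −2.39 in stomach, and Afp at 5.63, 4.39, 3.12 and 1.51. The liver list was also higher in lung, by 0.71, and was lower in stomach, at −1.57, and in esophagus, at −0.91. The split of 161 higher to 153 lower became 208 to 84 under median centring. Without the lung array the counts were 476 and 696, with 138 at 4-fold, and without the stomach array 307 and 321, with 70 at 4-fold.

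**Figure D2:**
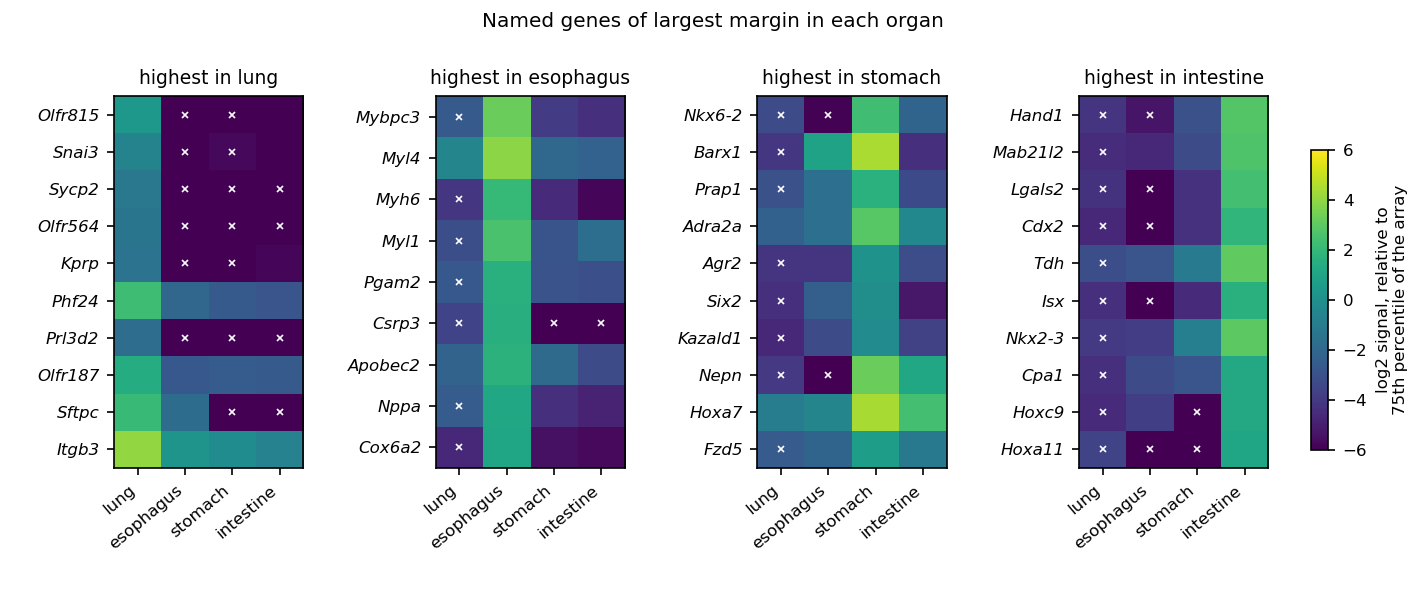
Log2 signal relative to the array's 75th percentile (colour) of the named genes of largest margin in each organ (rows; 10 in lung, stomach and intestine, 9 in esophagus) on the 4 arrays (columns); a white cross marks a gene not well above background on that array, and colours are cut off at −6 and 6. Mybpc3 stands at 3.24 in esophagus and Hand1 at 2.79 in intestine, and many of the lung cells of the other organs' genes carry a cross.

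The third comparison followed genes shared by a pair of organs or ordered along the tube. Esophagus and stomach shared 160 genes at least 2-fold above both of the others, led by Hs3st3b1 (at least 12.9-fold), Barx1 (at least 9.92-fold), Gjd3 (at least 5.98-fold) and Sox2 (5.29-fold). Lung and esophagus shared 125, led by Nkx2-1 (at least 25.5-fold), Nebl (19.3-fold), Foxd1 (16.9-fold) and Wnt2 (16.9-fold). Stomach and intestine shared 75, among them Syt10 (at least 49.97-fold), Cartpt (at least 13.02-fold) and Hoxb7 (12.6-fold). Lung and intestine shared 70, led by Alb (5.07-fold). Esophagus and intestine shared 11, led by Actc1 (3.26-fold), and lung and stomach shared 4, which were Trpv6, Maats1, Fgf10 and St8sia4. From esophagus through stomach to intestine, 141 genes fell at least 2-fold at each step, led by Tbx5 (15.5-fold at its smaller step, from esophagus to stomach), Myh8 (at least 13.6-fold) and Prrx1 (13.1-fold), a gene of limb and head mesenchyme. In the other direction 57 genes rose at least 2-fold at each step, led by Nkx2-3 (8.20-fold), Vil1 (6.70-fold), Saa3 (5.74-fold) and Saa2 (5.30-fold). Median centring gave 74 falling and 110 rising genes, quantile normalization 88 falling genes, and median centring 310 genes shared by lung and intestine and 57 shared by esophagus and stomach.

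The Hox genes, which pattern the body from head to tail by their number within a cluster, differed along the tube. Groups 9 to 13 were higher in intestine by a median of 1.70 (9 measured genes, 5 of them at least 2-fold above every other organ, above all random lists). Hoxa11 stood at 1.09 and Hoxc9 at 1.23 there. Hoxa10 and Hoxd10, at −0.26 and −0.27, were not well above background on any other array. Groups 5 to 8 were higher in stomach by 0.71 (10 measured genes, 3 at least 2-fold above every other organ, above all random lists) and lower in esophagus, at −0.80. Hoxa7 stood at 4.42 in stomach, 2.42 in intestine, −0.55 in esophagus and −0.91 in lung, and Hoxb8 at 0.68 in stomach. In lung, Hoxb5 stood at 3.37 and Hoxb6 at 3.41, above their levels in the gut segments. In groups 1 to 4 the median of largest size was 0.56, in lung (percentile 98.1 among random lists), which became 0.95 under median centring, 0.16 when all probes of a gene were averaged and 0.0770 under normexp. The median of groups 5 to 8 in esophagus was −2.53 with only the genes well above background on all 4 arrays and −1.85 with no filter on dim probes. In the other direction, it was −0.39 under normexp and −0.36 when all probes of a gene were averaged. Under normexp the median of groups 9 to 13 in intestine was −0.0919. It was 3.15 without the lung array, where the median of groups 5 to 8 in esophagus was −2.11; the latter was −1.86 without the intestine array and −0.48 without the stomach array. The median of groups 1 to 4 in lung was 0.33 without the intestine array.

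**Figure D3:**
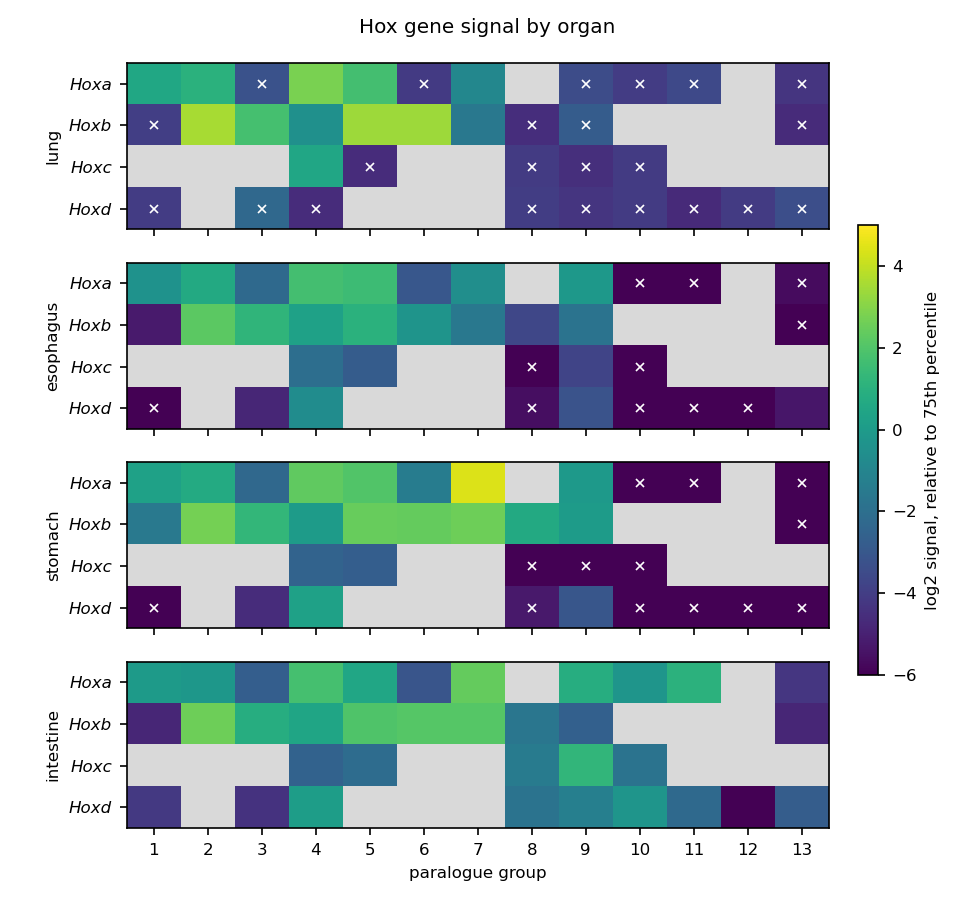
Log2 signal relative to the array's 75th percentile (colour) of each measured Hox gene, by cluster (rows) and paralogue group (columns), 1 panel per organ; a white cross marks a gene not well above background, and grey a gene with no measured probe. In intestine Hoxa11 stands at 1.09, while on the other 3 arrays it carries a cross.

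Further lists fixed before the data were examined covered other cell types and signalling pathways. Genes of enteric neurons and neural crest were higher in stomach by a median of 1.02 and in intestine by 1.07, and lower in lung, at −1.04, and in esophagus, at −0.48 (13 measured genes). Hand2 stood at 1.61 in stomach and 1.79 in intestine against −0.20 in esophagus, and Elavl4, a neuronal RNA-binding protein, at 2.20, 2.01 and 0.65. With only the genes well above background on all 4 arrays the median in intestine was −0.35, and under normexp it was −0.0949. Leaving out the lung array took it to 0.0448 (16 measured genes, percentile 48.7 among random lists), with 0.75 in stomach and −1.21 in esophagus. Erythroid genes were higher in lung by 0.99 (0.26 under normexp; 10 genes, all above the mean of the other organs), with embryonic globin Hbb-y at 8.87 in lung and 6.88 in esophagus. Epithelium genes were lower in intestine, at −0.73 (12 genes, −0.25 under normexp), where Foxa2 stood at −0.17 against 2.53 in stomach. Cell cycle genes had a median of −0.58 in esophagus (11 genes), where the middle 95% of random lists ran from −0.52 to −0.01, and it was −0.23 under normexp and −1.01 under median centring; at −0.33 without the lung array it lay within the random lists (percentile 14.6). Among the pathways, on all 4 arrays, the medians of largest size were −0.50 for FGF genes in esophagus (10 genes), −0.40 for Wnt genes in intestine (21 genes), −0.39 for retinoic acid genes in intestine (13 genes), −0.38 for BMP genes in esophagus (11 genes), 0.25 for Notch genes in esophagus (12 genes, −0.0733 under median centring and −0.10 under normexp) and −0.21 for Hedgehog genes in stomach (12 genes). Those of BMP and Hedgehog genes lay within the middle 95% of random lists (percentiles 10.7 and 9.4). Under normexp the medians were −0.11 for FGF, −0.19 for Wnt and −0.14 for retinoic acid and for BMP genes. With only the genes well above background on all 4 arrays Wnt genes stood at −0.81, FGF genes at −0.95, retinoic acid genes at −0.10 and Notch genes at 0.47, and with no filter on dim probes BMP genes stood at −0.01 and retinoic acid genes at −0.68. Median centring gave −0.85 for FGF, −0.24 for Wnt and −0.15 for retinoic acid genes, and the mean of all probes −0.95 for FGF, −0.00405 for retinoic acid and −0.13 for Hedgehog genes. Their order depended on single arrays, and so did the sign for retinoic acid genes. Without the lung array retinoic acid genes in intestine stood at −1.12, Wnt genes in intestine at −0.785, FGF genes in esophagus at −0.75, Hedgehog genes in stomach at −0.0639 and BMP genes in esophagus at −0.00397. Retinoic acid genes in intestine stood at −0.0234 without the esophagus array and at 0.0795 without the stomach array. Wnt genes in intestine stood at −0.20 and −0.66 under these settings. BMP genes in esophagus stood at −0.19 without the stomach array and −0.22 without the intestine array, and Notch genes in esophagus at 0.14 without the intestine array. Within the Wnt list, Rspo2, a potentiator of Wnt signalling, stood at 2.81 in lung, 0.00 in esophagus, −2.40 in stomach and −4.71 in intestine.

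The remaining lists, each at its median of largest size, were endothelium at −0.38 in stomach (10 genes, −0.23 under normexp), macrophages and other leukocytes at −0.52 in esophagus (10 genes, −0.28 under normexp and −0.95 under median centring), mesothelium at 0.32 in lung (8 genes, 0.59 under median centring and 0.81 with no filter on dim probes), stress response at −0.82 in lung (7 genes, 0.28 under normexp and −0.47 under median centring), pancreas at −1.09 in lung (5 genes, 0.28 under normexp and 0.57 with no filter on dim probes), spleen primordium at 0.38 in stomach (5 genes, 0.22 under median centring), cartilage at −0.69 in intestine (4 genes, −0.16 under normexp), urogenital ridge at −0.28 in intestine (3 genes, −1.59 under median centring and −1.71 under quantile normalization) and neural tube at 2.11 in stomach (2 genes, of which Nkx6-2 is 1, with −0.11 under normexp and −0.17 with no filter). Those of mesothelium, stress response, cartilage and urogenital ridge lay within the middle 95% of random lists (percentiles 84.99, 2.7, 2.7 and 7.6). Under the percentile over probes bright on all 4 arrays, mesothelium stood at 0.20 in lung and urogenital ridge at −0.14 in intestine. Xist and the Y-linked genes Ddx3y, Eif2s3y and Kdm5d were well above background on all 4 arrays and ran in opposite directions. Xist was highest in esophagus, 2.62-fold above lung, and the Y-linked genes were lowest there, by 1.65-fold, 1.73-fold and 1.42-fold below the next organ, so the median of this list, −1.12 in esophagus (4 genes; −0.26 under normexp and −0.63 without the lung array), does not describe Xist. Without the lung array the median of the neural tube list was 0.51 in stomach (8 measured genes) and that of the urogenital ridge list in intestine −0.13. The urogenital ridge list stood at −1.43 in intestine and the endothelium list at −0.61 in stomach without the esophagus array, the spleen primordium list at 0.68 in stomach without the intestine array, and the urogenital ridge list at −0.42 in intestine without the stomach array.

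**Figure D4:**
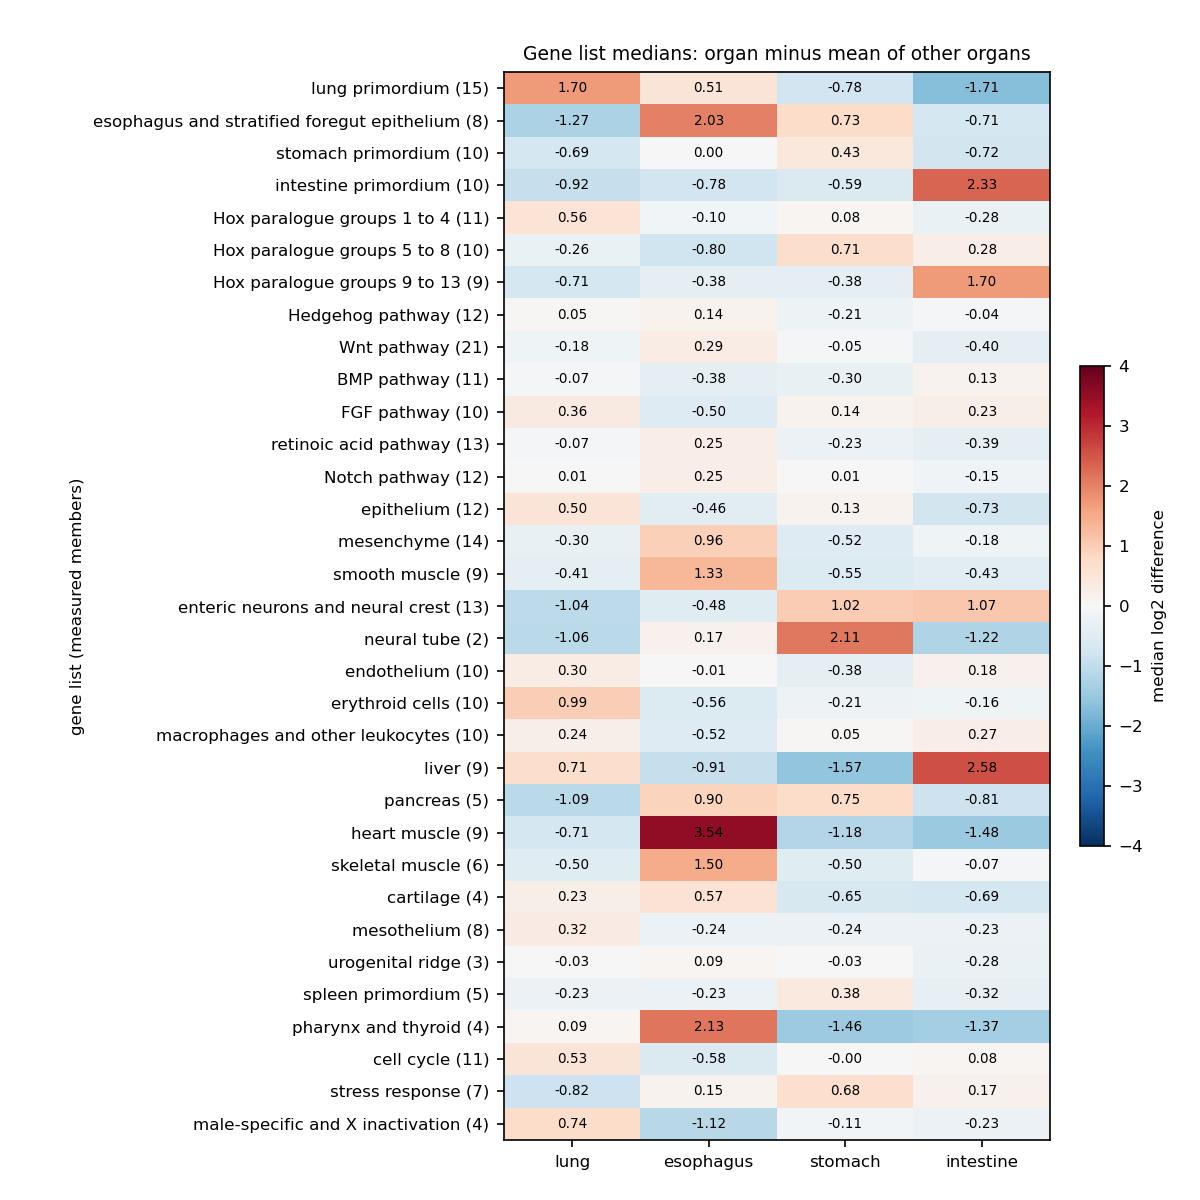
Median over the measured members of each gene list (rows, number of members in brackets) of the log2 value in 1 organ minus the mean of the other organs (columns and printed values). The largest median is 3.54 for heart muscle genes in esophagus.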

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

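Probes without a gene name were outside the comparisons of the report, and some of them also differed between organs. Of 16767 such probes, 303 were at least 2-fold higher in lung than in every other organ, 87 in esophagus, 9 in stomach and 38 in intestine. At 4-fold the counts were 70, 5, 2 and 6, against 69, 45, 9 and 38 for genes with a symbol. The probes without a name were flagged as a signal in data that the comparisons did not use, and no explanation was tested.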

How the results depend on the processing

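No paired analysis was possible because each organ has 1 array and no result comes from a test. Leaving out each array was chosen after the data were seen; the other settings were planned. The counts of genes kept within 1.5 times of the main value under the deposited series table, under leaving out saturated probes (of which there were 0) and under the mean of all probes. The deposited table nearly repeats the main values, so it was bound to agree, as was leaving out saturated probes. The r of a pair kept within the spread of the pairs, 0.0186, under all settings but those named here. That spread exceeds gaps between pairs such as 0.967 and 0.966, so it does not show that their order held. Signal over background limits the lung array: changes below its lowest level are found in part only. The cause of the changes below was not tested, except that an offset of 50 exceeds the lung signal of 33.4, that stricter or no filters change which genes enter, and that leaving out an array removes a condition.

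Under normexp with an offset of 50, genes 2-fold apart numbered 437 for esophagus and stomach. Genes above every other organ numbered 404 in lung, 85 in esophagus and 18 in stomach. Genes below every other numbered 846 in lung, 12 in esophagus and 11 in stomach. Genes shared by a pair numbered 66 in lung and esophagus, 27 in lung and intestine, 60 in esophagus and stomach, 3 in esophagus and intestine and 41 in stomach and intestine. Genes ordered along the tube numbered 76 falling and 21 rising. The r of lung and intestine was 0.886. List medians were 0.58 for lung primordium in lung, 0.25 for esophagus and stratified foregut epithelium in esophagus and 0.0770 for Hox paralogue groups 1 to 4 in lung. The median of stomach primordium in stomach was −0.10, and −0.11 with only genes bright on all 4 arrays, within the bootstrap error of a list median from 0.43. Other medians were −0.23 for cell cycle in esophagus, −0.25 for epithelium in intestine, −0.14 for the BMP pathway in esophagus and −0.19 for the Wnt pathway in intestine. List medians changed sign to −0.0848 for intestine primordium in intestine, −0.0919 for Hox paralogue groups 9 to 13 in intestine, −0.10 for Notch pathway in esophagus, −0.0949 for enteric neurons and neural crest in intestine, −0.11 for neural tube in stomach, 0.28 for pancreas in lung, −0.10 for skeletal muscle in esophagus and 0.28 for stress response in lung. Here too, list values were raised to the highest of the arrays' lowest levels. Members at that level on several arrays can give such small medians, which do not show a reversal between organs.

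Under quantile normalization, genes below every other numbered 51 in esophagus. Genes ordered along the tube numbered 88 falling.

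With arrays centred on the median, genes 2-fold apart numbered 4996 for lung and esophagus and 4720 for esophagus and intestine. Genes above every other organ numbered 1127 in lung, 83 in esophagus and 31 in stomach. Genes below every other numbered 174 in lung, 139 in esophagus and 84 in intestine. Genes shared by a pair numbered 7 in lung and stomach, 310 in lung and intestine, 57 in esophagus and stomach and 7 in esophagus and intestine. Genes ordered along the tube numbered 74 falling and 110 rising. List medians were 1.51 for esophagus and stratified foregut epithelium in esophagus and 0.95 for Hox paralogue groups 1 to 4 in lung. List medians changed sign to −0.0733 for Notch pathway in esophagus.

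With the percentile over probes bright on all 4 arrays, genes above every other organ numbered 332 in lung. Genes below every other numbered 540 in lung and 17 in esophagus.

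With only genes bright on all 4 arrays, genes 2-fold apart numbered 478 for esophagus and stomach, 1290 for esophagus and intestine and 663 for stomach and intestine. Genes above every other organ numbered 73 in esophagus, 24 in stomach and 83 in intestine. Genes below every other numbered 196 in lung. Genes shared by a pair numbered 104 in esophagus and stomach, 6 in esophagus and intestine and 39 in stomach and intestine. Genes ordered along the tube numbered 66 falling and 20 rising. List medians were 1.22 for intestine primordium in intestine and −2.53 for Hox paralogue groups 5 to 8 in esophagus. List medians changed sign to −0.35 for enteric neurons and neural crest in intestine.

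With no filter on dim probes and no bounds, genes 2-fold apart numbered 7528 for lung and esophagus, 7253 for lung and stomach, 6887 for lung and intestine, 2105 for esophagus and stomach, 4739 for esophagus and intestine and 3484 for stomach and intestine. Genes above every other organ numbered 4021 in lung, 270 in esophagus, 93 in stomach and 243 in intestine. Genes below every other numbered 716 in lung, 366 in esophagus, 198 in stomach and 1731 in intestine. Genes shared by a pair numbered 484 in lung and esophagus, 174 in lung and stomach, 365 in lung and intestine, 259 in esophagus and stomach, 20 in esophagus and intestine and 128 in stomach and intestine. Genes ordered along the tube numbered 268 falling and 87 rising. The r of esophagus and intestine was 0.960. List medians were −1.85 for Hox paralogue groups 5 to 8 in esophagus. List medians changed sign to −0.17 for neural tube in stomach and 0.57 for pancreas in lung.

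With the mean of all probes, list medians were 0.16 for Hox paralogue groups 1 to 4 in lung.

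With each array left out in turn, genes above every other organ ranged from 181 to 577 in esophagus, 152 to 245 in stomach, 186 to 476 in intestine and 731 to 1091 in lung. Genes below every other ranged from 37 to 303 in esophagus, 124 to 202 in stomach, 186 to 696 in intestine and 355 to 618 in lung. List medians ranged, among others, from 1.30 to 2.27 for esophagus and stratified foregut epithelium in esophagus, −2.11 to −0.48 for Hox paralogue groups 5 to 8 in esophagus, 2.06 to 3.15 for Hox paralogue groups 9 to 13 in intestine, 0.58 to 1.01 for stomach primordium in stomach, where all 4 arrays gave 0.43, 0.33 to 0.73 for Hox paralogue groups 1 to 4 in lung, 0.0448 to 1.20 for enteric neurons and neural crest in intestine, lowest without the lung array, 0.51 to 2.44 for neural tube in stomach, −1.12 to 0.0795 for the retinoic acid pathway in intestine, a change of sign, −0.22 to −0.00397 for the BMP pathway in esophagus, −0.785 to −0.20 for the Wnt pathway in intestine, −0.28 to −0.0639 for the Hedgehog pathway in stomach and −1.43 to −0.13 for urogenital ridge in intestine.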

Other observations

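The tests of heart and liver tissue, of skeletal muscle alone, of spot scatter and of the intestine's own transcripts were chosen after the results they bear on were seen. The tests of single bright spots, of weak signals, of a common probe effect and of fetal liver blood were recorded before their values were seen, but the reading of the fetal liver blood test was changed after its value was seen. The test of different transcripts was recorded before its own value was seen, but it was added after the spot scatter test had come out. The reading that its bound gave was not kept. Narrower tests of single bright spots, on the muscle and liver members alone, were added after the wider ones had been seen, and both values are given. A planned weighing of the chemoreceptor genes among the lung-high genes was set aside after the data were seen, and its values are given at the end without an explanation.

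Heart muscle transcripts on the esophagus array: 9 of 9 measured heart genes were at least 2-fold above every other organ, which heart tissue in the dissected sample, beside the esophagus in the embryo, could account for. For skeletal muscle progenitors alone, the test used genes that skeletal muscle does not use (Nppa, Myl7, Myh6, Tnni3, Tbx20), whose median margin was 3.48. These are among the 9 genes that make the pattern, so a margin of at least 2-fold was known in advance. The value shows only that such genes were high too, and it is no independent test. Single bright spots remain a candidate explanation for part of the esophagus-high genes by the test as first written, since 46.6% of 58 second probes pointed the same way, under the 60% set beforehand, though above the 25.8% of all genes with a second probe. On the muscle genes alone 4 of 5 second probes did, too few to decide. Myl2 and Nppb, of the ventricle, stood at −2.50 and −3.93 in esophagus. These low levels do not show that transcripts of the ventricle are absent. Without the lung array, 10 of 11 heart members were at least 2-fold higher in esophagus than in stomach and intestine. Whether the signal comes from a part of the heart or from muscle of the esophagus itself was not tested.

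Lung ratios that differ between probes of a gene: 60.2% of 528 second probes shared the sign of a 2-fold difference between lung and stomach. Weak signals cannot be excluded. Among genes whose probes both lie above the lung array's 75th percentile, the share was 65.0% of 246 (95% Wilson interval 58.9 to 70.7%). The share met the bound set beforehand to argue against weak signals, but its interval runs past that bound. The percentile is also a low signal, 33.4 in lung against 334 in stomach. Spot scatter is argued against as the main source by its size, 0.0935 of the SD between probes. That value sets the SD over spots on the lung array alone against a difference of ratios from lung and stomach, so it understates the share of scatter. For lung probes below the 75th percentile the SD over spots was 0.18, against 1.12 between probes. Probes that read different transcripts cannot be told apart: 507 of the 528 genes have probes of the same accession, so the share among them, 60.4%, nearly repeats the share of all. The share met the bound set beforehand to argue against different transcripts, but that reading was not kept. It excludes nothing for probes of 1 accession that meet different forms of the transcript. An effect of the probe common to several arrays stays open and may contribute, since the difference between probes correlated across genes at r = 0.38 between lung over stomach and intestine over esophagus, ratios with no array in common. Of the other pairings of that kind, lung over esophagus with stomach over intestine gave r = −0.60, and lung over intestine with esophagus over stomach gave 0.17, short of the size of 0.3 set beforehand for the first pairing. The sign turns with the direction in which each ratio is taken, so only the sizes can be compared across pairings. What such an effect would be (amplification, RNA quality, distance from the transcript end) was not tested.

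Liver transcripts on the intestine array: 8 of 9 measured liver genes were at least 2-fold above stomach and esophagus, and liver tissue in the dissected sample could account for this. The intestine primordium's own transcripts cannot be told apart from it: the median log2 difference between intestine and stomach of Alb, Ahsg and Fgb, products of the liver, was 5.37, but these are among the genes that make the pattern, were picked with their values known, and would differ as much if the primordium itself expressed them. Blood cells of the fetal liver cannot be told apart: the erythroid list differed by 0.0673, under the bound that was set beforehand to argue against them. That reading was given up after the value was seen, because the list already stood at a median of 1.87 in stomach, which would hide a small share. Single bright spots stay open for the intestine-high genes, as 67.4% of 43 second probes pointed the same way, between the bounds set beforehand, and the 3 second probes of liver genes (from Apob and Hhex), all higher in intestine, are too few to decide. With 1 array per organ, a difference between the organs themselves stays open and untested.

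The chemoreceptor genes well above background numbered 12 in lung, 172 in esophagus, 246 in stomach and 398 in intestine, and 8, 0, 0 and 0 of them were at least 2-fold above every other organ. The median level of the lung-high genes in lung was 1.59, against 1.34 for all genes well above background there, and second probes pointed the same way for 47.5% of the lung-high genes, against 38.1% of all genes with a second probe, and for 46.6% of the esophagus-high genes, against 25.8%.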
